A study of Schizophyllum amplum with 15 samples.

How the data were processed

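Polyadenylated RNA with an RNA integrity number above 8 was made into libraries with a kit whose protocol, as the labels describe it, has no step that marks the strand, so overlapping antisense transcripts cannot be told apart. The 15 libraries cover 5 developmental stages with 3 biological replicates each, and each library was placed in its stage by its title. The submitters' processing notes name R 3.0.2, edgeR 3.4.2 and limma 3.18.13; the aligner, genome build and annotation are not given in the sources used here.

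Each library file lists 15576 gene models with a gene length, unique and total gene reads, an expression value, TPM and RPKM. The deposited total gene reads are whole-number counts per gene model, not normalized, and the expression value is the same number in all 15 files. The deposited TPM values sum to the same total in every library, to within 1. The RPKM column of the library files is 0 throughout in all 15 and was not used. A separate table of the series holds log2 RPKM values made by the authors: its lowest value is -7.24, and for gene models with over 50 reads in a library its values differed from log2 of RPKM computed from the counts by a nearly constant offset per library, of at most 0.158, with an SD over gene models of at most 0.00329. Lower counts were not compared. That deposited table holds 14345 gene models; each has 5 or more reads in at least 4 libraries, and the 1231 left out have that in at most 3. The deposited gene lengths give no position, since every gene model is its own reference sequence, so no genome coordinates are given. Reads matching a single place made up 98.16% to 98.53% of the counts per library; 350 tested gene models had under 50% of such reads and 82 had none, and their levels depend on how the authors divided reads between copies.

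The main test used the total gene reads. With R 4.3.3 and edgeR 4.0.16, gene models were filtered by filterByExpr on the 5 stages, which kept 14022 and left out 1554 holding at most 0.0241% of a library's reads; libraries were scaled by TMM, and 1 quasi-likelihood model was fitted to all 15 libraries (common biological coefficient of variation 0.199, prior degrees of freedom 4.36). Each stage was compared with the one before it and the last with the first, a joint test covered the 5 stages, and calls were made at a Benjamini-Hochberg adjusted p under 0.05. Standard errors were derived from the log2 change and its F value. CPM are TMM-scaled, and log2 CPM used a prior count of 2. The design, the alternatives and the rule for single gene models were fixed before the data were examined: without product names, the 2 largest rises and 2 largest falls of each comparison were named among gene models with an adjusted p under 0.05, CPM that did not overlap between the 2 stages and a mean count of at least 100 in the higher one. Gene lists by function had also been fixed, but neither product names nor sequences were used here, so those tests were not run. Ratios for gene models with 1 to 3 reads in a stage use summed reads over TMM-scaled depth with an exact 95% binomial interval, which covers counting error only.

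The libraries held 11532152 to 28318107 reads. Summed over gene models, replicates of a stage differed by far more than sampling noise, with a chi-square per degree of freedom of 13.96 to 86.97, so no library was counted as a repeat of another. In counts simulated without pairing for the comparison of the primordium stages over 13968 gene models, 62% of gene models changed 2-fold and 91% of those changed 4-fold were called, and 13 unchanged ones were called; for mycelium against stage 1 primordium over 13969 gene models the shares were 60% and 91%.

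Replicate numbers are shared across stages in the titles. For the primordium stages, the deviations of same-numbered libraries from their stage means correlated over gene models at 0.24, 0.44 and 0.19 for replicates 1, 2 and 3. The numbers were therefore taken to pair those libraries, from the data and not from the labels. No chance level was computed for these correlations, and replicate 2 also reached 0.34 between mycelium and stage 1 primordia. The pairing is thus an assumption. The main fit, planned without covariates, leaves this pairing out, and it enters only where the replicate number is a block. No other comparison had a correlation above 0.1 for every number.

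The alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, uniquely matching reads, the replicate number as a block, only the 2 stages compared, limma 3.58.1 on log2 of the deposited RPKM (returned from the log2 scale) with a pseudocount of 1 or 0.1, with or without a filter at an RPKM of 1 in 3 libraries, and leaving out each library in turn.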

Results

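Messenger RNA of Auriculariopsis ampla, a wood-inhabiting mushroom related to the split-gill fungus, was sequenced at 5 stages of fruiting body development, with 3 biological replicates per stage. Strain NL-1724 was grown on poplar bark and wood, first in darkness for 14 days (30 °C) and then at room temperature with 12 hours of light a day. Primordia appeared after 7 days of light. Vegetative mycelium is the thread-like growth that feeds on the wood, and primordia, sampled as stage 1 and stage 2, are the first organised knots of tissue. Young and mature fruiting bodies completed the series, and the mature ones are called fruiting bodies here. The libraries held 11532152 to 28318107 reads assigned to gene models. The mean depth was 15742069 ± 4130642 reads in mycelium, 15137237 ± 5281031 in stage 1 primordia and 18127896 ± 3722175 in stage 2 primordia (SD, n = 3 each). It was 19971777 ± 5942149 in young fruiting bodies and 18737466 ± 8470051 in fruiting bodies. Of 15576 gene models, 14022 had enough reads to be tested. The files do not pair the gene model identifiers with names or functions, so they are described by the groups of stages in which they were high or low, and single ones by the identifier in the files.

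Vegetative mycelium stood apart from every fruiting stage. On the first principal component of log2 CPM, the log of counts scaled to a common library size, which held 63.3% of the variance, the 3 mycelium libraries lay between -148 and -134 and the other 12 between 24.8 and 42.6. The second component, with 20.4% of the variance, placed both primordium stages between -45.2 and -27.8, young fruiting bodies between -4.37 and 24.4 and fruiting bodies between 53.5 and 91.9. The mean root-mean-square difference of log2 CPM between a mycelium and a stage 1 primordium library was 1.61, against 0.481 between mycelium replicates and 0.533 between stage 1 primordium replicates. Between stage 1 and stage 2 primordia it was 0.541, close to the 0.519 found between stage 2 replicates.

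**Figure D1:**
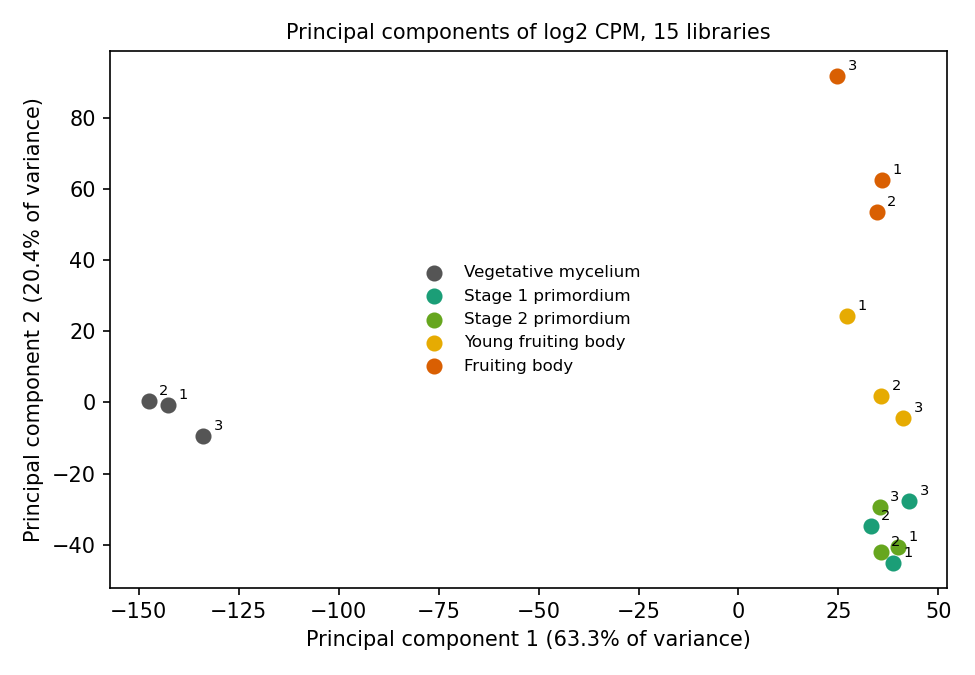
Principal components of log2 CPM of the 14022 tested gene models; each point is 1 of the 15 libraries, coloured by stage and numbered by replicate. Mycelium lies apart on the first component (63.3% of the variance), and fruiting bodies lie highest on the second (20.4%).

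The step from vegetative mycelium to stage 1 primordium addressed which genes differ between mycelium and the first primordia. The growth conditions are recorded alike for every stage and do not say when the mycelium was taken. Light, temperature and culture age therefore cannot be told apart from fruiting in any comparison with mycelium. A large part of the measured genes changed at this step: 4259 gene models rose and 4252 fell, together 60.7% of those tested. The median absolute change was 0.68 on the log2 scale. At least 4-fold, 1146 gene models rose and 827 fell. The 2 largest named rises were in short models with almost no mycelium reads. The level of jgi|Auramp1|549857|, of 453 bases, went from 0.295 CPM ± 0.26 in mycelium to 610 ± 220 in stage 1 primordia (SD, n = 3 each). That of jgi|Auramp1|409280|, of 429 bases, went from 0.127 ± 0.097 to 400 ± 85. In the other direction jgi|Auramp1|460572| went from 1140 CPM ± 330 to 2.51 ± 0.36. For jgi|Auramp1|407999| 1325 reads were counted over the mycelium libraries and 1 read over the stage 1 libraries, a ratio of 1210 in depth-adjusted counts with an exact 95% counting interval of 217 to 47900.

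The test was edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, as in each comparison. By edgeR with that adjustment the log2 change was 10.95 (SE 0.72, adjusted p = 1.35e-08) for jgi|Auramp1|549857|, 11.40 (SE 0.419, adjusted p = 7.18e-11) for jgi|Auramp1|409280| and -8.84 (SE 0.391, adjusted p = 2.7e-10) for jgi|Auramp1|460572|. In limma on log2(RPKM + 1) these changes were 9.62, 9.40 and -8.17, and without mycelium replicate 1 the 2 rises were 11.67 and 12.32. No read of jgi|Auramp1|409280| matched a single place. For jgi|Auramp1|549857| and jgi|Auramp1|460572| the share was 83.4% and 75.9%, so the levels of these 3 are uncertain where reads were divided between near-identical copies.

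Stage 1 and stage 2 primordia differed in few gene models: 5 rose and 6 fell. The level of jgi|Auramp1|478125| rose from 24.1 CPM ± 10 to 94 ± 24 and jgi|Auramp1|522822| from 21.6 ± 6.4 to 72.8 ± 21 (SD, n = 3 each). Both were also above the stage 1 level in mycelium, at 76.7 ± 14 and 258 ± 21 CPM. Nearly absent from mycelium at 0.402 CPM ± 0.088, jgi|Auramp1|223077| fell from 159 ± 66 to 31.4 ± 17. Abundant in mycelium at 234 CPM ± 63, jgi|Auramp1|571795| fell from 9.38 ± 3.6 to 2.37 ± 0.13.

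By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes of these 4 were 1.97 (SE 0.322, adjusted p = 0.0423), 1.75 (SE 0.265, adjusted p = 0.0423), -2.34 (SE 0.399, adjusted p = 0.0484) and -1.96 (SE 0.304, adjusted p = 0.0423), in that order. Of the reads of jgi|Auramp1|522822| 64.7% matched a single place, and of those of jgi|Auramp1|223077| 77.8%. The total of 11 was 0 in edgeR with the replicate number as a block (1345 models at an unadjusted p under 0.05, against 1234 without it) and 85 in DESeq2. It was 0 without stage 1 replicate 2 or without stage 2 replicate 2, 1 without stage 1 replicate 1, 4 without stage 1 replicate 3 and 167 without stage 2 replicate 3.

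From stage 2 primordium to young fruiting body 431 gene models rose and 216 fell, 19 and 3 of them at least 4-fold. The excess of rises depended on the fit: DESeq2 gave 888 that rose and 873 that fell, and without stage 2 primordium replicate 2 edgeR gave 113 and 10. Both of the largest named rises were in models that were abundant in mycelium and low in primordia. One, jgi|Auramp1|564023|, stood at 441 CPM ± 81 in mycelium and went from 14 ± 7.3 in stage 2 primordia to 89.2 ± 65 in young fruiting bodies (SD, n = 3 each). The other, jgi|Auramp1|492563|, stood at 258 CPM ± 67 in mycelium and went from 67 ± 13 to 417 ± 460. The 2 largest named falls were in models of 156 bases that were almost unread in mycelium. Of these jgi|Auramp1|403040| fell from 9.06 CPM ± 1.1 to 2.09 ± 0.7 and jgi|Auramp1|419383| from 27.8 ± 2.3 to 7.73 ± 0.36.

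With edgeR's quasi-likelihood test and Benjamini-Hochberg adjustment these log2 changes were 2.65 (SE 0.485, adjusted p = 0.0104), 2.64 (SE 0.6, adjusted p = 0.0277), -2.08 (SE 0.472, adjusted p = 0.0277) and -1.84 (SE 0.401, adjusted p = 0.0227). Without young fruiting body replicate 1 the change of jgi|Auramp1|492563| was 1.16 and missed the threshold, and the change of jgi|Auramp1|564023| was 1.87. Over the alternative settings and left-out libraries together, jgi|Auramp1|564023| missed the threshold in 1, jgi|Auramp1|492563| in 7, jgi|Auramp1|403040| in 4 and jgi|Auramp1|419383| in 6. The total of 647 was 154 and 198 without young fruiting body replicates 1 and 2, 198, 123 and 1102 without stage 2 primordium replicates 1, 2 and 3, 1761 in DESeq2 and 363 when only these 6 libraries were fitted. The 19 became 9 without stage 2 primordium replicate 2 and 49 without its replicate 3.

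Maturation from young to mature fruiting body changed more gene models than the earlier steps among fruiting stages: 1981 rose and 1590 fell, 117 and 32 of them at least 4-fold. The level of jgi|Auramp1|454931| rose from 6.19 CPM ± 5.3 to 84.2 ± 60 and jgi|Auramp1|635718| from 0.566 ± 0.27 to 9.09 ± 8.9 (SD, n = 3 each). Both were below 10 CPM at each earlier stage. In contrast jgi|Auramp1|568873| had its highest level in stage 1 primordia, 646 CPM ± 270. It went through 229 ± 120 in stage 2 primordia and 103 ± 59 in young fruiting bodies to 12 ± 1.5 in fruiting bodies. Likewise jgi|Auramp1|180275| was low in fruiting bodies: it was highest in the middle stages, with 64.1 CPM ± 48 in stage 2 primordia and 85 ± 72 in young fruiting bodies, and fell to 11.3 ± 0.31.

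The log2 changes from young to mature fruiting body were 3.82 (SE 0.667, adjusted p = 0.00196), 3.99 (SE 0.842, adjusted p = 0.00507), -3.11 (SE 0.464, adjusted p = 0.000856) and -2.91 (SE 0.71, adjusted p = 0.0102) by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of the reads of jgi|Auramp1|635718| 61.8% matched a single place. Without young fruiting body replicate 2 the change of jgi|Auramp1|180275| was -1.96 and missed the threshold. The change of jgi|Auramp1|635718| was 2.95 without fruiting body replicate 3 and 2.15 in limma on log2(RPKM + 1), and that of jgi|Auramp1|454931| was 4.74 without young fruiting body replicate 1. The total of 3571 was 1544 without fruiting body replicate 3, 1926 without young fruiting body replicate 2 and 1654 without young fruiting body replicate 3. The 117 that rose at least 4-fold became 44 in limma on log2(RPKM + 1), 60 without fruiting body replicate 3 and 181 without young fruiting body replicate 1, and the 32 that fell became 49 without fruiting body replicate 2.

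Between the ends of the series, fruiting body against vegetative mycelium, 4562 gene models rose and 4194 fell, 1370 and 650 of them at least 4-fold. The largest named rises were in short models. The level of jgi|Auramp1|399056|, of 396 bases, went from 0.784 CPM ± 0.28 to 1890 ± 510, and that of jgi|Auramp1|570972|, of 453 bases, from 0.941 ± 0.13 to 1580 ± 200 (SD, n = 3 each). The first was already at 1120 CPM ± 520 in stage 1 primordia, while the second stood at 149 ± 55 there and at 401 ± 95 in young fruiting bodies. A model of 273 bases, jgi|Auramp1|571486|, fell from 1300 CPM ± 320 to 3.88 ± 1.2. For jgi|Auramp1|407999| there were 3 reads over the fruiting body libraries against 1325 in mycelium, a ratio of 538 with an exact 95% counting interval of 184 to 2610.

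By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment the log2 changes were 11.17 (SE 0.722, adjusted p = 9.85e-09) for jgi|Auramp1|399056|, 10.71 (SE 0.456, adjusted p = 1.72e-10) for jgi|Auramp1|570972| and -8.39 (SE 0.39, adjusted p = 3.59e-10) for jgi|Auramp1|571486|. Counting error alone enters the 2 intervals of jgi|Auramp1|407999|. The 1370 rises of at least 4-fold were 898 in limma on log2(RPKM + 1), a scale on which changes of low gene models are understated, and the change of jgi|Auramp1|570972| was 10.11 there.

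**Figure D2:**
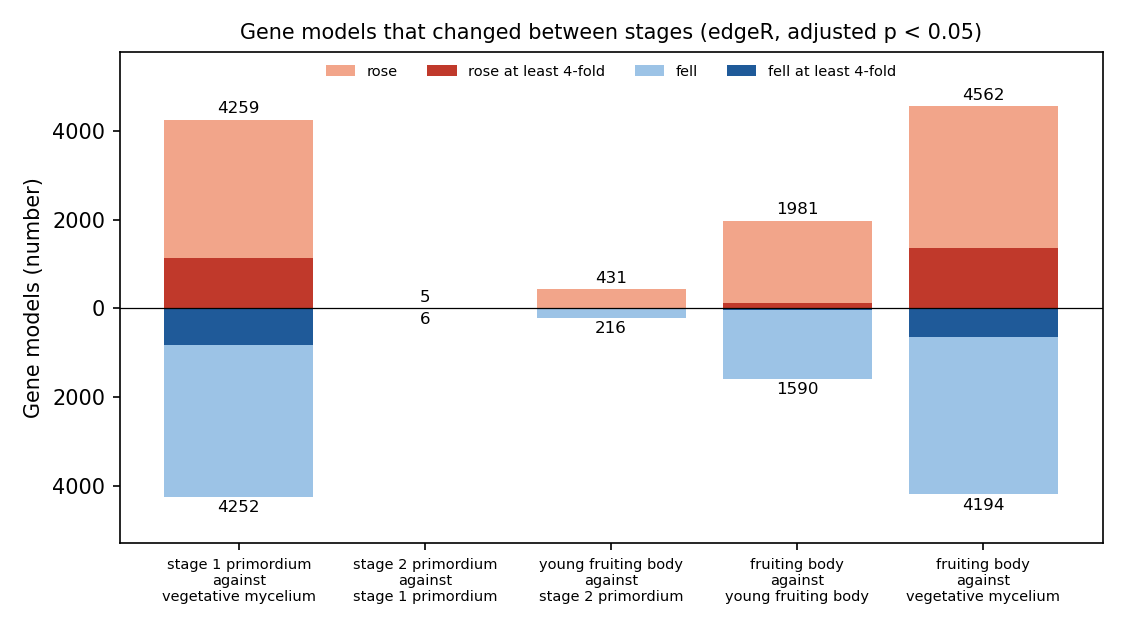
Number of gene models that rose (above 0) or fell (below 0) in each of the 5 comparisons at an edgeR adjusted p under 0.05, with those changed at least 4-fold in the darker shade. The comparisons with mycelium have 8511 and 8756 in all, and that between the primordium stages has 11.

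Much of what separated mycelium from fruiting bodies was already present in stage 1 primordia. Of the 1370 rises of at least 4-fold from mycelium to fruiting bodies, 838 were also at least 4-fold by stage 1. Another 227 were not called there. Of the 650 falls of at least 4-fold, 499 were also at least 4-fold by stage 1 and 21 were not called there. Of the 1146 gene models that had risen at least 4-fold by stage 1, 1097 were also higher in fruiting bodies than in mycelium and 3 were lower. Of the 827 that had fallen at least 4-fold, 732 were also lower in fruiting bodies and 2 were higher. At least 4-fold in both comparisons, 838 rose and 499 fell, where independent lists of these sizes share 112 and 38.3. Both comparisons use the same 3 mycelium libraries. In 10 simulations without any effect those overlaps were 0, but a mean of only 0.1 gene models rose and 0.1 fell at least 4-fold by stage 1. An overlap of 0 was thus fixed in advance and does not show what the shared controls add to the 838 and 499. In those simulations the correlation of the log2 changes over gene models was 0.50 and their covariance 0.037, against 0.84 and 2.24 observed. The 3 mycelium libraries could not be divided into sets of at least 2, and part of the excess may come from the shared controls.

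Over the 5 stages, 11315 gene models (80.7%) differed in edgeR's joint quasi-likelihood test, and 3082 (22% of those tested) also spanned at least 4-fold between their highest and lowest stage. Of the 3082, the highest level was in fruiting bodies for 1149 and in mycelium for 1044, against 422 in stage 1 primordia, 288 in stage 2 primordia and 179 in young fruiting bodies. The lowest level was in mycelium for 1640. These places rest on the fitted levels alone, without a test against the stage next in rank. In the main fit 0 gene models were at least 4-fold above each other stage in stage 1 primordia. The same held for stage 2 primordia and for young fruiting bodies. The 1149 models highest in fruiting bodies were 661 in limma on log2(RPKM + 1), fewer than the 778 highest in mycelium there.

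At the ends of the series, groups of gene models stood apart from all other stages. In mycelium 452 gene models were at least 4-fold above each other stage. These mycelium genes made up 10.7% ± 1.5 of TPM, the authors' length- and depth-scaled level, there and between 0.501% ± 0.033 and 0.637% ± 0.058 at the other stages (SD, n = 3 each). The counterpart was a group of 749 fruiting genes, at least 4-fold lower in mycelium than at each other stage, which held 0.763% ± 0.36 of TPM in mycelium and 18.4% ± 1, 19.3% ± 0.43, 18.9% ± 0.99 and 22.2% ± 1.3 in the 4 fruiting stages in order of development. In fruiting bodies 83 gene models were at least 4-fold above each other stage, and their share of TPM went from 0.0589% ± 0.0073 in mycelium and 0.284% ± 0.043 in young fruiting bodies to 1.87% ± 0.73. A group of 30 primordium genes, defined after the values were seen as at least 4-fold higher in both primordium stages than in both mycelium and fruiting bodies, held 0.0409% ± 0.011 of TPM in mycelium, 1.36% ± 0.16 and 1.15% ± 0.16 in the primordium stages, 0.749% ± 0.29 in young and 0.236% ± 0.17 in mature fruiting bodies.

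Each membership required an adjusted p under 0.05 in every pairwise edgeR quasi-likelihood test and a log2 difference of at least 2. The 83 became 43 without fruiting body replicate 3 and 39 in limma on log2(RPKM + 1), where the 749 became 491. The 30 became 59 without fruiting body replicate 2. In mycelium replicate 3 the 749 held 1.172% of TPM, against 0.575% and 0.541% in mycelium replicates 1 and 2. Without mycelium replicate 3 the 749 became 815.

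**Figure D3:**
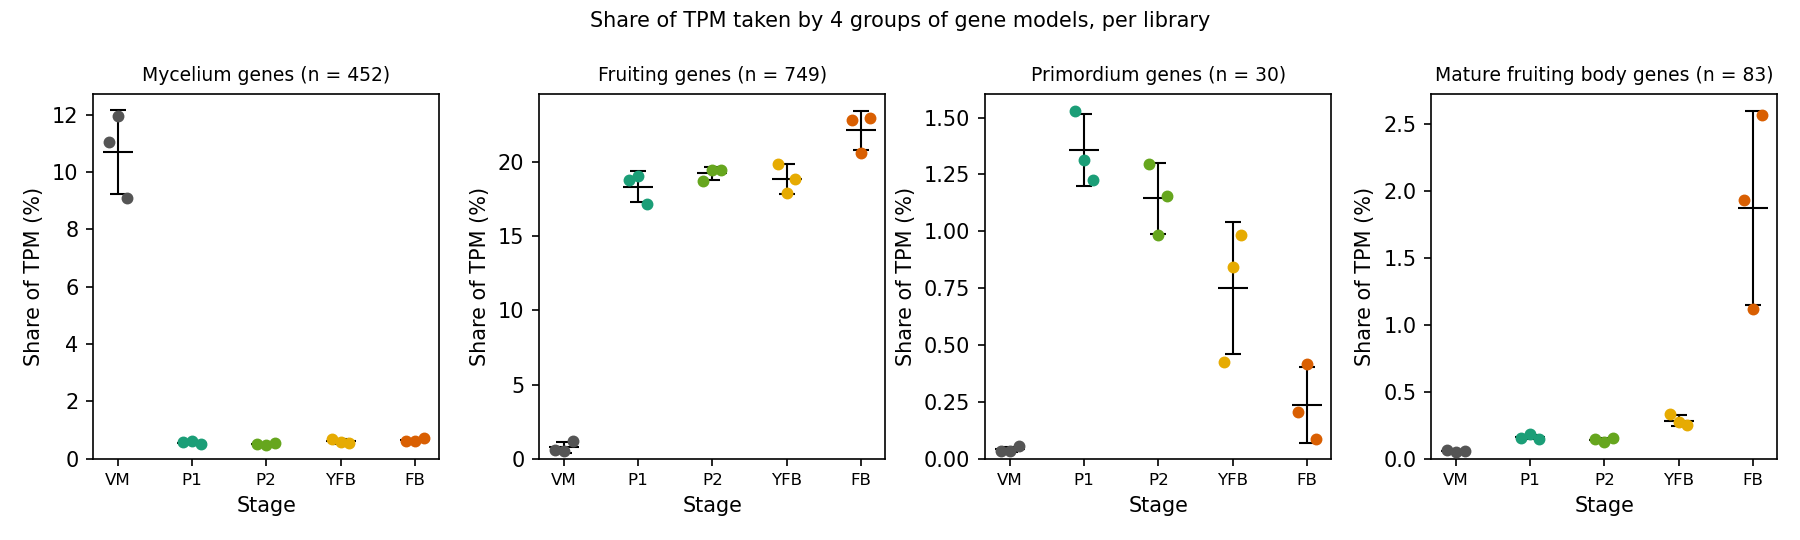
Share of TPM (%, vertical axis, starting at 0) held by 4 groups of gene models at each stage (VM, vegetative mycelium; P1 and P2, stage 1 and stage 2 primordium; YFB, young fruiting body; FB, fruiting body); points are libraries, dashes are means and bars are SDs (n = 3). The 452 mycelium genes hold 10.7% in mycelium, the 749 fruiting genes 18.4% to 22.2% at the fruiting stages, and the 83 mature fruiting body genes 1.87% in fruiting bodies.

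A single transcript led all 12 libraries of the fruiting stages. This model, jgi|Auramp1|548479|, of 1110 bases, was singled out after its values were seen. It took 0.0064% ± 0.00092 of the reads in mycelium, 2.51% ± 0.098 in stage 1 and 3.6% ± 0.57 in stage 2 primordia, 4.26% ± 1.3 in young and 2.68% ± 0.36 in mature fruiting bodies (SD, n = 3 each). By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment its log2 change from mycelium to stage 1 primordium was 8.69 (SE 0.386, adjusted p = 2.7e-10), and from young to mature fruiting body it was -0.80 (SE 0.278, adjusted p = 0.0471). Its share was 5.79% in young fruiting body replicate 1 against 3.4% and 3.58% in replicates 2 and 3. The fall was not examined with a library left out. Another, jgi|Auramp1|486614|, singled out in the same way, was the model most often next in rank in these libraries. It took 1.43% ± 0.17 of the reads in stage 1 primordia against 0.0874% ± 0.11 in mycelium. The 10 most read models together took 4.05% ± 0.0565 of the reads in mycelium and 7.07% ± 0.2 to 8.44% ± 0.526 at the fruiting stages.

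Later changes often ran against the change at the start of fruiting. The step from mycelium to stage 1 primordium and the step from young to mature fruiting body share no library, and 2268 gene models were called in both. Of these, 757 had risen and then fell and 711 had fallen and then rose, where independent lists give 483 and 601. Another 476 rose in both and 324 fell in both, where independent lists give 602 and 482. Opposite directions thus made up 64.7%, and over all tested gene models the log2 changes had a Pearson r of -0.14 and a Spearman rho of -0.21, across gene models, which are not independent replicates. With the step from stage 2 primordium to young fruiting body, also without a shared library, 491 were called in both and 60.3% went in opposite directions. In that pair 121 rose and then fell (65.6 for independent lists), 175 fell and then rose (130.7), 164 rose in both (130.9) and 31 fell in both (65.5). Same-numbered stage 1 and stage 2 primordium libraries were, however, taken as paired. A deviation that they share enters these changes with opposite signs and favours opposite directions. The counts for independent lists do not allow for this, so that pair is not independent support. Leaving out 1 library at a time gave 55% to 70.9% opposite directions in the first pair.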

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

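The fit of the primordium stages alone with the replicate block, and the other fits of the primordium gene group and of the group high in both mycelium and fruiting bodies, were chosen after the results were seen. Stage 1 primordium against mycelium stayed within 7846 to 8661 gene models over the alternatives and 7706 to 8197 with 1 library left out; fruiting body against mycelium stayed within 8473 to 8928 and 7922 to 8300. The joint test gave 10596 to 11659 over all of them, and at least 4-fold 2092 to 3270. Stage 2 against stage 1 primordium (11) gave 85 with DESeq2, 19 with uniquely matching reads and 0 to 167 with 1 library left out. It gave 0 in edgeR with the replicate block, 0 with only these 2 stages and 0 with both. At an unadjusted p under 0.05 these fits held 1345 of 14022, 917 of 13492 and 1495 of 13492 tested. A share of 0.05 would fall there without any change. Young fruiting body against stage 2 primordium (647) gave 1761 with DESeq2, 363 with only these 2 stages and 123 to 1102 with 1 library left out. Fruiting body against young fruiting body (3571) stayed within 3296 to 4181 over the alternatives and gave 1544 to 3734 with 1 library left out. The cause was not tested, except that fits to 2 stages or with a library left out hold fewer libraries. With the replicate block the other counts were 8661, 692, 3743 and 8863 in order of the comparisons, 11460 in the joint test and 3073 at least 4-fold; outside the primordium stages the replicates share only a number. The 4 named models of the primordium comparison missed the threshold under 7 or 8 settings each, and over all named models 49 of 297 values did so and 0 turned direction. The alternatives for gene lists were not run, because the lists could not be matched.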

Other observations

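The tests of mycelium RNA in fruiting body libraries, of the distance from mycelium, of a difference shared by replicate number and of young fruiting body replicate 1, the gene group high at both ends of the series and the division by expression level were chosen after the results were seen. A group of 47 gene models was at least 4-fold higher in both mycelium and fruiting bodies than in both primordium stages by edgeR's pairwise tests. It held 1.05% ± 0.18 of TPM in mycelium, 0.0394% ± 0.0054 and 0.0459% ± 0.011 in stage 1 and stage 2 primordia, 0.146% ± 0.092 in young fruiting bodies and 0.334% ± 0.17 in fruiting bodies (SD, n = 3 each); without fruiting body replicate 3 it had 28 members. Another 227 gene models were at least 4-fold higher in fruiting bodies than in mycelium without a call in stage 1 primordia, against 21 that were at least 4-fold lower in that way. Fruiting bodies differed from stage 1 primordia in 7206 gene models, 3751 higher and 3455 lower, of which 526 and 77 by at least 4-fold. Young fruiting bodies differed from stage 1 primordia in 1435.

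Gene models that rose at least 4-fold from mycelium to stage 1 primordium had a median length of 1131 bases. It was 1252 for those that fell and 1278 for all tested. A two-sided permutation test of the difference between those that rose and fell gave p = 0.0016 (100000 permutations). It treats gene models as independent and does not measure spread between libraries. The median was lower for those that rose in each of 4 bands of mean expression. It was 829 against 939 bases in the lowest band and 1417 against 1667.5 in the highest. The bands used the mean over all 15 libraries, of which 3 were mycelium. Models that rose and fell were thus not matched by their highest level. The authors' log2 table leaves out 1 gene model that passes the filter used here, jgi|Auramp1|407999|, which has the largest fall among the gene models open to naming in both comparisons with mycelium. All 49 gene models with 5 or more reads in exactly 3 libraries are left out of that table.

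Few gene models changed between the primordium stages, 11 against 647 and 3571 in the next steps, and leaving out stage 2 replicate 3 gave 167 while leaving out replicate 2 of either stage gave 0. A wider spread in primordia as the whole account is argued against by a median SD of log2 CPM only 1.16 times that of the other stages. Low power for 2-fold changes stays open. In counts simulated without pairing 62% of them were called, but with 100 models changed 2-fold and 100 changed 4-fold. That many true changes make the adjusted threshold easier to pass than in a comparison with 11 calls, and the real libraries were taken as paired. Smaller changes stay open as well. The fit with the replicate block called 0 but held 1345 of 14022 gene models at an unadjusted p under 0.05. A share of 0.05 of the 14022 would fall there without any change. An exchange of labels stays open as a hypothesis. Dividing the 6 libraries with stage 1 replicate 2 and stage 2 replicate 3 exchanged called 146, several times the real count, which points to a structure of these samples. The most read model took 2.41% to 2.6% of reads in stage 1 libraries and 3.2% to 4.25% in stage 2 libraries as labelled. It was singled out after its values were seen. Its log2 change was 0.625 (SE 0.277, adjusted p = 0.544 by edgeR's quasi-likelihood test), so it weighs little against an exchange. That division keeps the libraries numbered 2 together and those numbered 3 together, so a difference shared by replicate number may also give it; its correlation over gene models with mycelium replicate 2 minus replicate 3 was 0.15, between the bounds of 0.1 and 0.2 set for that test, and the question stays open. A true likeness of the primordium stages was not tested against either.

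Gene models called both at the start of fruiting and at maturity more often went in opposite directions, and r was -0.14 over all tested gene models between these comparisons, which share no library. The criterion set beforehand for a move back toward mycelium, r below a fixed negative bound with mostly opposite directions, was thus met. By measures chosen later, the profile as a whole did not come nearer to mycelium. The mean root-mean-square distance of log2 CPM from mycelium was 1.63 for fruiting bodies and 1.55 for young fruiting bodies. Each of the 3 mycelium libraries lay farther from every fruiting body library than from every young one. From mycelium, 8756 gene models differed in fruiting bodies against 8148 in young ones. These measures also grow with changes unrelated to mycelium, so they cannot exclude a partial return. On the first principal component, which parts mycelium, fruiting bodies lay at 24.8 to 36.0 and young ones at 27.1 to 41.2, ranges that overlap. A return of part of the gene models stays open at r = -0.14. Mycelium carried into the fruiting body samples is argued against as the whole cause by 173 gene models at least 16-fold higher in mycelium than in stage 1 primordia. Over these, the rise from young to mature fruiting bodies implied a median mycelium share of 0.764% (quartiles 0.0654% to 2.29%). Of the 711 gene models that had fallen and then rose, 680 had a higher level in mycelium than in young fruiting bodies. They needed 89% (42.9% to 177%). These 680 were picked for having risen, which raises the share they need, so the 89% is not separate evidence. Of those 173, 29 rose and 8 fell at maturity. No other account of the opposite directions was tested, a changing mix of cell types included.

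Young fruiting body replicate 1 lay apart from the other 2, at 24.4 on the second principal component against -4.37 and 1.72. Its difference from them correlated over gene models with the difference between fruiting bodies and stage 2 primordia at r = 0.42, and with the difference between mycelium and stage 2 primordia at r = 0.28, so the likeness is not to fruiting bodies alone; its place on that component, which parts these stages, already implies the former, and a more advanced stage stays open. Shallow sequencing is argued against by r = 0.5 over the 4736 gene models of at least 50 CPM, and an exchange with a fruiting body library by the component, on which 0 fruiting body libraries lay below it. The 30 primordium genes held 0.424% of TPM in this library against 0.842% and 0.982% in the other 2, which mixing would need 56% mycelium or 72.2% mature tissue to give, while 472 mycelium gene models implied 1.71% and 243 gene models high in fruiting bodies implied 14.9%, so mixing is argued against as the source of that fall and a smaller share of mature tissue stays open for the rest. Without this library, 154 gene models changed from stage 2 primordium to young fruiting body and 3734 from young to mature fruiting body.

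Other divisions of the libraries were counted with the same edgeR test. With 3 libraries against 3 there are 10, too few for a share under 0.05. The real division gave 8511 gene models for stage 1 primordium against mycelium and the highest other 0; 647 and 3 for young fruiting body against stage 2 primordium; 3571 and 119 for fruiting body against young fruiting body; and 8756 and 0 for fruiting body against mycelium, so that 1 of 10 reached the real count in each. For the primordium stages, 2 of 10 reached 11, the highest other being 146; among the 4 divisions that part all 3 numbered pairs the other 3 gave 0, and the one with 146 parts 1 pair. Of 100 divisions of all 15 libraries, 1, the real one, reached 11315 in the joint test (highest other 4763) and 1 reached 3082 at least 4-fold (highest other 2049), which excludes chance at a share of 0.05.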
